A study of Homo sapiens with 12 samples.

How the data were processed

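Small RNA from exosomes of the human breast adenocarcinoma line MDA-MB-231 was sequenced in 12 samples, 3 in each of 4 groups: parental cells and sorted CSC-like (cancer stem cell-like) cells, each untreated or treated with cisplatin. Per the labels' protocols, cells were kept in serum depleted of exosomes, RNA was extracted with an exosome RNA kit and libraries were made with a multiplex small RNA kit. The submitters' processing notes name cutadapt and FastQC. The aligner, the number of mismatches it allowed, the genome build and the miRNA reference release are not given in the sources used here. Whether the replicates came from separate cultures is not given either, so the p-values measure only the spread between these samples, which may be technical.

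The authors deposited 1 table per cell population. Per the file headers, each table holds whole read counts per mature miRNA and replicate, not transformed and not normalized. The deposited tables also hold a score per miRNA, the authors' signed fold change of weighted proportions, in which an n-fold fall is written as a negative number. The last deposited column is a p-value, which per the file headers comes from Baggerley's test on the untransformed proportions and is not adjusted for multiple testing. There are 137 miRNAs listed for parental and 114 for CSC-like exosomes, and each listed miRNA has at least 1 count in each group of its table. No miRNA with counts in only 1 group of a table is therefore listed, so a complete loss or gain with cisplatin cannot be seen. In each file 1 line was not analysed here.

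Depth was low. Listed counts ranged from 2648 to 6622 per parental library and from 429 to 2522 per CSC-like library. A count of 0 allows a share of up to 0.0453% in the deepest library and up to 0.699% in the shallowest (3 counts of the total). Shares of single libraries are given with exact (Clopper-Pearson) 95% intervals. These intervals and floors cover counting error only, since no molecular identifiers are given for the reads. The authors' fold for miRNAs with 1 count in each group had a median size of 1.3852 in the parental table and 1.6116 in the CSC-like table, beside ratios of the listed group totals of 1.3849 and 1.6027. The listed totals were therefore used as library sizes.

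Replicate libraries were compared by a chi-square test over miRNAs with at least 10 counts in the pair. Replicates 2 and 3 of cisplatin-treated CSC-like cells did not differ detectably beyond sampling noise (chi-square per degree of freedom 1.18, p = 0.212), whereas the other pairs of that group did (10.1 and 8.08). Their counts were summed and the pair was counted as 1 sample, which leaves 2 samples in that group. Its mean and SD use the mean share of the pair. Replicates 2 and 3 of cisplatin-treated parental cells had a ratio of 1.48 (Monte Carlo permutation p = 0.011, chi-square p = 0.0123) and were kept apart. They held 3552 and 3924 counts, against 1877 and 1575 in the summed pair, where the test can detect less. The different handling of these pairs may therefore reflect depth.

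Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr with its defaults (minimum count 10, minimum total 15), TMM normalization, the quasi-likelihood test and Benjamini-Hochberg adjustment within each table, with a threshold of 0.05. The filter kept 37 miRNAs in the parental table, 29 in the CSC-like table and 30 in the comparison of both untreated groups. The response in CSC-like cells was set against that in parental cells as an interaction term in 1 model over the 4 groups, on 48 of the 98 miRNAs that both tables list. Standard errors of log2 fold changes were taken from the fold change and the quasi-likelihood F statistic. Lists of miRNAs with at least 3 tested members were tested with limma's camera (preset correlation 0.01, and an estimated one) and fry, adjusted over the lists of a table. Shares of lists were compared by a two-sided exact permutation test. With 3 samples against 3 its smallest p is 0.1.

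On simulated counts drawn for the listed miRNAs with 6 changed miRNAs per simulation, 20 simulations each, the test recovered 21.7% of 4-fold and 85.8% of 16-fold changes in the parental design (37 tested). In the CSC-like design (29 tested) it recovered 20.0% and 84.2%, and in the design of both untreated groups (30 tested) 10.8% and 80.0%. The interaction test recovered 41.7% of 16-fold changes (48 tested). Wrong calls numbered 1 and 5 over the simulations of the parental design, 1 and 4 over those of the CSC-like design, 2 and 5 over those of both untreated groups and 2 over those of the interaction. For lists, with every tested member of 1 list raised 4-fold in 20 simulations, camera recovered 18 lists in the parental and 19 in the CSC-like design (37 and 29 miRNAs), and fry 9 and 4. With no change simulated, camera called 0 of 100 and 2 of 60 lists and fry 0 of 100 and 0 of 60. Each miRNA was drawn independently of the others, so these rates for lists do not cover lists whose members vary together between libraries, as the let-7 family did. The step for lists was added after the results were seen.

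The tests, the 17 lists, most of the alternatives and the rule for named miRNAs were fixed before the data were examined. The untreated groups were at first compared by a contrast over all 4 groups, which called 5 miRNAs; the planned model on these 2 groups alone, reported here, called 1. The rule takes the 10 largest rises and falls past the threshold in each comparison, up to 4 members of each list past it, every listed member of the let-7 family, the miR-200 family and the blood cell and serum miRNAs, and the 5 most abundant miRNAs of each table. Other miRNAs were named after their values were seen: those with an unadjusted p under 0.05 here, those with an adjusted p under 0.05 from the authors' p-values, and, for the interaction and the untreated groups, the miRNAs called elsewhere. Alternatives covered stricter and looser thresholds, a minimum fold change, Bonferroni adjustment, no filter on low counts, DESeq2 1.42.0 size factors with its Wald test, a replicate block, each library left out in turn, and counts summed over the arms and copies of a precursor. For the last one a mean of fold changes had been planned, and summed counts were used since the tables hold counts. The pseudocount planned for normalized values was not run.

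Positions of mature sequences come from exact matches to GENCODE v29 transcripts (GRCh38). Matches of tested miRNAs with up to 2 mismatches were searched in its 206694 transcripts. Genome sequence outside annotated transcripts was not used here. miRNAs that differ by few bases, such as let-7 members, may share reads, and their single values are uncertain for that reason.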

Results

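Exosomes, small vesicles that cells release, carry miRNAs that can be counted by small RNA sequencing. The libraries came from exosomes of MDA-MB-231, a human breast adenocarcinoma line, grown as parental cells or as sorted CSC-like cells, with or without 56 µM cisplatin for 48 h. Cisplatin is a platinum drug that crosslinks DNA. Untreated parental libraries held 3527, 2648 and 4005 miRNA counts, and cisplatin-treated parental libraries 6622, 3552 and 3924. Untreated CSC-like libraries held 1526, 2172 and 2522 counts, and cisplatin-treated CSC-like libraries 429, 1877 and 1575. A difference beyond sampling noise was not detected between replicates 2 and 3 of the last group, which were counted as 1 sample, so that n = 2 there.

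A few miRNAs made up most of the counts. miR-21-5p, a miRNA abundant in many tumours, was the most abundant miRNA in 10 of the 12 libraries, and miR-100-5p in untreated parental replicates 1 and 3. The let-7 family, miRNAs linked to differentiation and to repression of RAS, made up 0.851% of counts in untreated parental replicate 1 (exact 95% interval 0.575 to 1.21), against 28.1% in replicate 2 and 14.6% in replicate 3. In the other 9 libraries its share lay between 8.86% and 19.5%. let-7i-5p, miR-4488 and miR-146a-5p, an inhibitor of NF-kB signalling, completed the 5 most abundant miRNAs of both tables.

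**Figure D1:**
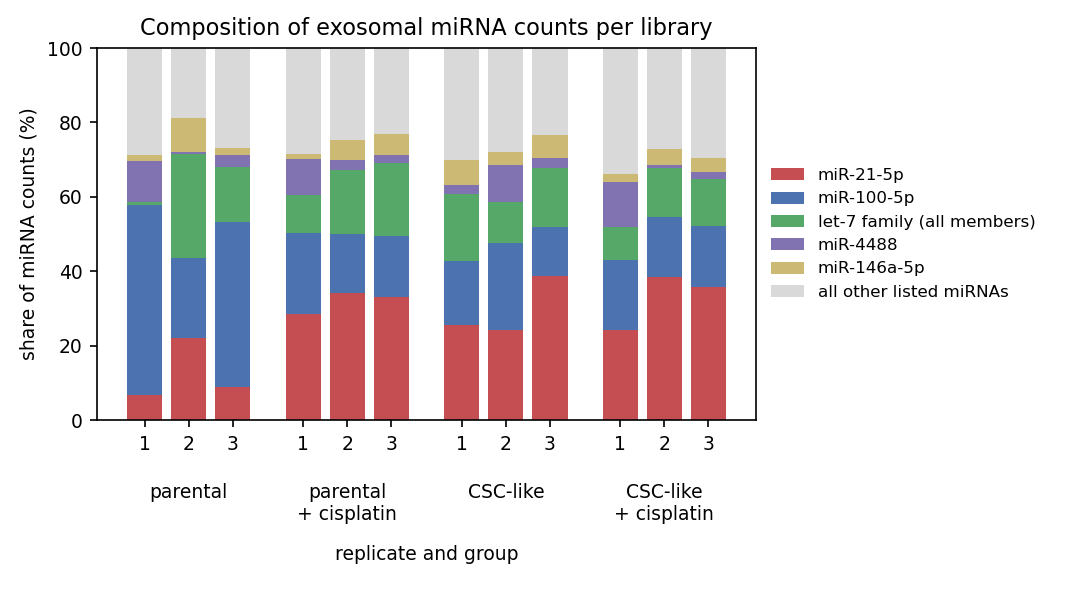
Share of miRNA counts (percent, vertical axis) taken by miR-21-5p, miR-100-5p, the let-7 family, miR-4488, miR-146a-5p and all other listed miRNAs in each of the 12 libraries (replicate 1, 2 and 3 of each group, horizontal axis). The let-7 share of untreated parental replicate 1, 0.851%, is the smallest of the 12.

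The first comparison asked which exosomal miRNAs differed after cisplatin in parental cells. miR-30b-5p and miR-7-5p rose, and no miRNA fell past the threshold. miR-30b-5p, a member of the miR-30 family linked to an epithelial state, was counted 1, 1 and 3 times in the untreated libraries and 19, 21 and 21 times in the treated ones, that is 0.0470% ± 0.0246 (SD, n = 3) against 0.471% ± 0.162 (SD, n = 3) of counts. miR-7-5p, which targets the EGF receptor, was counted 1, 2 and 3 times without and 22, 21 and 20 times with cisplatin, or 0.0596% ± 0.0271 against 0.478% ± 0.132 (SD, n = 3 each). In edgeR's quasi-likelihood test the log2 fold change was 2.97 (SE 0.64, adjusted p = 0.00336) for miR-30b-5p and 2.69 (SE 0.62, adjusted p = 0.00386) for miR-7-5p. Each was higher in 3 of 3 treated libraries than in any untreated one. The groups did not overlap for 16.2% of the 37 tested miRNAs, beside the 10% that chance gives.

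In GRCh38 the mature miR-30b-5p sequence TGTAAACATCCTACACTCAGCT lies on the minus strand of chromosome 8, from 134800570 to 134800591, in MIR30B, outside other annotated genes. The miR-7-5p sequence TGGAAGACTAGTGATTTTGTTGTT is encoded at 3 loci, whose counts cannot be told apart. They are MIR7-1 on chromosome 9 (83969811 to 83969834, in an exon of 1 annotated transcript of HNRNPK), MIR7-2 on chromosome 15 (88611856 to 88611879, intergenic) and MIR7-3 on chromosome 19 (4770700 to 4770723, in an intron of MIR7-3HG).

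Of the most abundant miRNAs, miR-21-5p made up 12.5% ± 8.38 of counts in untreated and 31.9% ± 2.92 in treated parental exosomes (SD, n = 3 each), with a log2 fold change of 1.02 (SE 0.66) that did not pass the edgeR test (adjusted p = 0.333). miR-100-5p, which targets mTOR, made up 39.0% ± 15.6 and 18.0% ± 3.12 (log2 fold change -1.43, SE 0.56, adjusted p = 0.139, edgeR). miR-7704 (log2 fold change -2.21, SE 0.76), miR-25-3p (-1.57, SE 0.63) and miR-10400-5p (-2.14, SE 1.00) also had an unadjusted p under 0.05 in edgeR and adjusted p-values of 0.0871, 0.139 and 0.244. These miRNAs differed by less than the spread between libraries allows to be called. Both miR-21-5p (1.81, adjusted p = 0.00013) and miR-100-5p (-1.70, adjusted p = 1.25e-07) passed without untreated parental replicate 2, together with miR-25-3p, miR-7704 and 4 others including miR-30b-5p and miR-7-5p, 8 in all.

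The miR-30 family had 3 tested members, of which miR-30b-5p rose, while miR-30a-5p (log2 fold change 0.49) and miR-30d-5p (-0.33) did not pass. The share of the 7 listed members was 1.5% ± 0.28 untreated and 2.74% ± 0.35 treated (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). fry called the family higher (adjusted p = 0.0227), whereas camera, which sets it against the other miRNAs, did not (adjusted p = 0.378, and 0.532 with an estimated correlation). The fry call was lost without any 1 of the 3 untreated parental libraries and without cisplatin-treated parental replicate 3. Among the 9 listed growth- and invasion-associated miRNAs, which include miR-21, 4 were tested and none passed. Their share was 14.2% ± 8.05 and 33.9% ± 2.54 (SD, n = 3 each; exact permutation p = 0.1), and the list did not pass in fry (adjusted p = 0.142) or camera (adjusted p = 0.667).

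None of the 5 tested let-7 members passed, and 4 of them had lower fitted values. let-7a-5p had a log2 fold change of -2.29 (SE 1.13, adjusted p = 0.244) and let-7b-5p of -1.46 (SE 0.71, adjusted p = 0.244) in edgeR, let-7f-5p of 0.53, and let-7i-5p and let-7g-5p of -0.09 and -0.10, signs that turn positive with library totals in place of TMM. The family's share was 14.5% ± 13.6 untreated and 15.6% ± 4.84 treated (SD, n = 3 each; exact permutation p = 0.9), and neither camera (adjusted p = 0.854) nor fry (adjusted p = 0.905) called it. Without untreated replicate 1 camera called the family lower (adjusted p = 0.0383, median log2 fold change -0.66; fry adjusted p = 0.14), whereas the median turned to 0.99 without untreated replicate 2 and to 0.08 without cisplatin-treated replicate 1, with no call. Over all leave-outs the camera adjusted p ranged from 0.0383 to 0.871. let-7c-5p, let-7d-5p, let-7d-3p and let-7e-5p had at most 9 counts in any library and were not tested. Of the miR-17-92 cluster and its paralogs 3 members were tested, all with lower fitted values, and none passed (fry adjusted p = 0.264). The miR-23-27-24 clusters likewise had 3 tested members and no call (fry adjusted p = 0.881).

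The other lists had fewer than 3 tested members. The miR-99/100 and miR-125 families made up 40.4% ± 16.6 untreated and 18.7% ± 3.32 treated (SD, n = 3 each; exact permutation p = 0.2). Adjusted over the list alone, 1 of their 2 tested members, miR-100-5p, passed as lower, and adjusted over the list alone miR-30b-5p passed in the miR-30 family. The entries overlapping other structured RNAs, mostly miR-1246, made up 2.66% ± 3.25 and 0.94% ± 0.87 (SD, n = 3 each; exact permutation p = 0.6). The miR-200 family, which holds the epithelial state, was represented by miR-200b-3p with 4, 0 and 5 counts untreated and 4, 7 and 8 treated, and by miR-429 with 1 count in each group. Blood cell and serum miRNAs were rare as well. miR-486-5p had 13 counts untreated and 5 treated, miR-126-3p 1 and 9, and miR-122-5p 6 and 8, together 0.18% ± 0.15 and 0.19% ± 0.17 of counts (SD, n = 3 each). p53-responsive, miR-15/16, miR-29, miR-181 and muscle and neuron miRNAs each made up at most 0.32% of counts in either group. No member of the pluripotent stem cell clusters, the chromosome 14 imprinted clusters or the chromosome 19 primate cluster was listed, which leaves open counts in only 1 of the groups.

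In the authors' deposited table, adjusting its p-values over the 137 listed miRNAs left 6 miRNAs under 0.05, all higher: miR-30b-5p, miR-7-5p, miR-22-3p, miR-21-5p, miR-29a-3p and miR-30c-5p. miR-22-3p was counted 1, 1 and 2 times untreated and 12, 21 and 17 times treated, but did not reach the count filter used here. With at least 15 counts over the libraries as the filter, it passed the edgeR test beside miR-30b-5p and miR-7-5p.

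Of the 37 tested miRNAs, 6 had an unadjusted p under 0.05 in edgeR, 2 higher and 4 lower. TMM placed the median log2 fold change of all tested miRNAs at -0.27 and library totals at 0.02, and fold changes are relative to that. Neither miR-30b-5p nor miR-7-5p was called without the low-count filter (log2 fold change 3.09 and 2.84, adjusted p = 0.0826 for both), without untreated replicate 1 (2.73 and 2.39, adjusted p = 0.139 for both; let-7a-5p and let-7b-5p were then called lower) or without untreated replicate 3 (3.43 and 2.87, adjusted p = 0.0698 and 0.0726). Over all alternatives the log2 fold change ranged from 2.73 to 3.43 and from 2.39 to 2.94, and the adjusted p from 1.47e-07 to 0.139 and from 3.07e-07 to 0.139.

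The second comparison asked the same of CSC-like cells. miR-3135b rose from 0.174% ± 0.163 (SD, n = 3) to 5.41% ± 1.26 (SD, n = 2) of counts, with 0, 7 and 5 counts in the untreated libraries and 27, 79 and 76 in the treated ones. Its log2 fold change was 4.67 (SE 0.88, adjusted p = 2.38e-05, edgeR), and it was higher in 2 of 2 treated samples than in any untreated one. The groups did not overlap for 13.8% of the 29 tested miRNAs, below the 20% that chance gives for 3 samples against 2. No miRNA fell past the threshold. Its sequence GGCTGGAGCGAGTGCAGTGGTG lies on the minus strand of chromosome 6 in GRCh38, from 32749952 to 32749973, in MIR3135B outside other annotated genes. With bases counted from 1 at its 5' end, it differs by A7T and G8C from the first bases of RNY3, the gene of Y3 RNA on chromosome 7 (148983755 to 148983856).

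**Figure D2:**
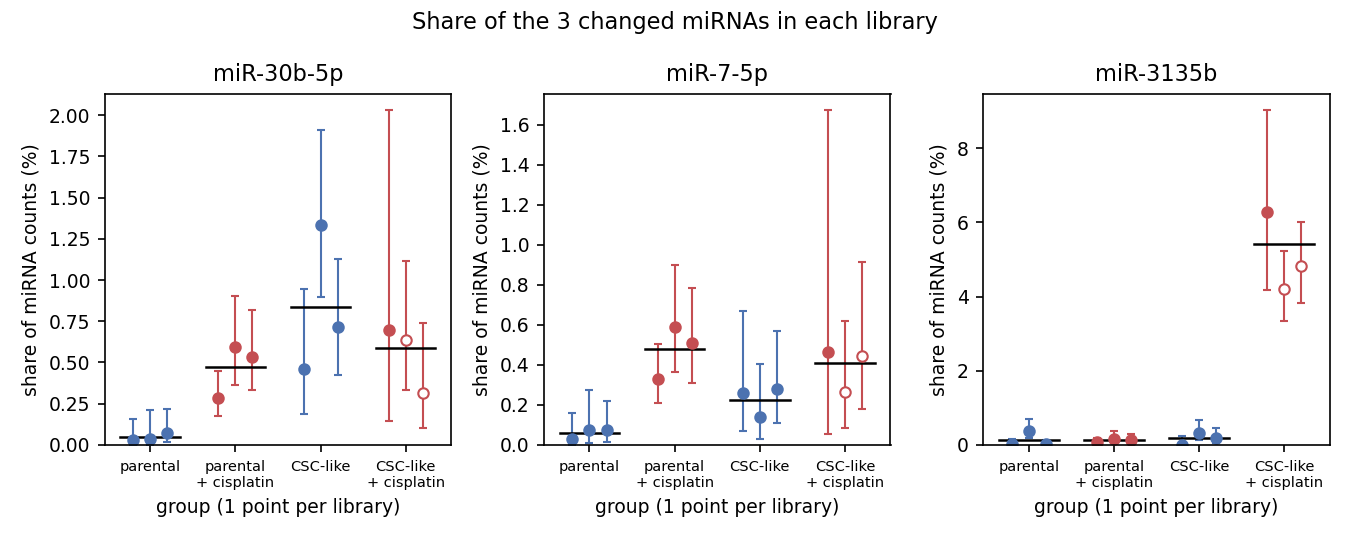
Share of miRNA counts (percent, vertical axis of each panel, starting at 0) of miR-30b-5p, miR-7-5p and miR-3135b in each library, by group (horizontal axis), with exact 95% intervals as bars, group means as black lines, untreated libraries in blue and cisplatin-treated ones in red; open circles mark the pair of libraries counted as 1 sample. The share of miR-3135b lies between 4.21% and 6.29% in the cisplatin-treated CSC-like libraries and at or below 0.378% in the other 9.

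miR-221-3p, often raised in invasive breast cancer, made up 1.05% ± 0.189 (SD, n = 3) of counts in untreated and 3.33% ± 1.89 (SD, n = 2) in treated CSC-like exosomes, and its log2 fold change of 1.5 (SE 0.80) did not pass the edgeR test (adjusted p = 0.613). miR-10400-5p (log2 fold change -1.83, SE 0.87, adjusted p = 0.561) had an unadjusted p under 0.05. miR-21-5p stood at 29.5% ± 8.06 and 30.7% ± 9.12 (SD, n = 3 and 2; log2 fold change 0.02, SE 0.59) and miR-100-5p at 17.9% ± 5.28 and 17.5% ± 1.93 (log2 fold change -0.14, SE 0.63). A change was not detected in either with this number of samples and this spread between them. The sign of miR-100-5p turns with DESeq2 size factors.

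The let-7 family made up 15.03% ± 3.59 (SD, n = 3) untreated and 10.9% ± 2.85 (SD, n = 2) treated (exact permutation p = 0.3). All 5 tested members had lower fitted values with TMM, of which let-7a-5p and let-7i-5p turn positive with DESeq2 size factors, and none passed. let-7f-5p had the lowest, -1.0 (SE 0.79). The median of the family turned to 0.08 without untreated CSC-like replicate 1. fry gave the family an unadjusted p of 0.047 and an adjusted p of 0.141, and camera an adjusted p of 0.626. The 3 tested members of the miR-30 family, with a share of 3.95% ± 1.58 untreated and 2.29% ± 1.92 treated (SD, n = 3 and 2), did not pass either (fry adjusted p = 0.536). miR-30b-5p itself stood at 0.836% ± 0.451 and 0.589% ± 0.156 (log2 fold change -0.72, SE 0.94). The 4 tested members of the miR-23-27-24 clusters showed no call (fry adjusted p = 0.887).

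Growth- and invasion-associated miRNAs made up 31.3% ± 8.23 (SD, n = 3) untreated and 35.01% ± 7.32 (SD, n = 2) treated. The miR-99/100 and miR-125 families stood at 18.3% ± 5.42 and 18.2% ± 2.23, and the miR-17-92 cluster and its paralogs at 1.21% ± 1.11 and 1.05% ± 0.17. The entries overlapping other structured RNAs stood at 0.73% ± 0.26 and 0.66% ± 0.38. miR-200b-3p and miR-429 together had 7 counts untreated and 9 treated, or 0.11% ± 0.02 (SD, n = 3) and 0.23% ± 0.01 (SD, n = 2). The treated libraries stood at 0.23%, 0.37% and 0.06%, and replicates 2 and 3 were averaged, so the small treated SD does not measure their spread. Of the blood cell and serum miRNAs miR-126-3p, miR-486-5p and miR-451a were listed with at most 3 counts in a library, as were let-7d-5p and let-7e-5p. The miR-15/16, miR-29, miR-181, p53-responsive and muscle and neuron miRNAs and the chromosome 14 imprinted clusters each made up at most 0.49% in either group. In the authors' deposited table, adjusting over its 114 miRNAs left miR-3135b and miR-221-3p higher and miR-3960 and let-7f-5p lower under 0.05.

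Of the 29 tested miRNAs, 2 had an unadjusted p under 0.05 in edgeR, miR-3135b and miR-10400-5p. The call of miR-3135b ended without untreated CSC-like replicate 1, which held 0 of its counts (log2 fold change 4.47, adjusted p = 0.0508), and with a replicate block on the 3 separate treated libraries (4.83, adjusted p = 0.346). Its adjusted p ranged from 7.36e-06 to 0.346 over all alternatives.

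The third comparison set the response in CSC-like cells against that in parental cells. miR-3135b differed between the populations, with a difference of 5.09 between the log2 fold changes (SE 1.49, adjusted p = 0.0358, edgeR interaction term). In parental exosomes its share was 0.144% ± 0.203 untreated and 0.129% ± 0.0392 treated (SD, n = 3 each). miR-30b-5p, called in parental cells only, had a difference of -3.16 (SE 1.23, adjusted p = 0.166), so its response was not shown to differ, although it passed with library totals in place of TMM (adjusted p = 0.0283). miR-7-5p did not pass either (-1.69, SE 1.31, adjusted p = 0.789; 0.568 with library totals). Across the 27 miRNAs tested in both tables, which are not independent replicates, 16 had fold changes of the same sign (Pearson r = 0.12, permutation p = 0.54; Spearman rho = 0.05, permutation p = 0.81). No miRNA was called in both tables. The interaction call of miR-3135b held in 7 of 16 alternatives. It was lost with a replicate block on separate libraries (5.13, adjusted p = 0.0588) and on leaving out any 1 of 8 libraries. The adjusted p was 0.549 without untreated parental replicate 2 (difference 3.13), 0.103, 0.123 and 0.237 without cisplatin-treated parental replicates 1, 2 and 3, 0.239, 0.0667 and 0.0735 without untreated CSC-like replicates 1, 2 and 3, and 0.0941 without cisplatin-treated CSC-like replicate 1. Over all alternatives it ranged from 0.0225 to 0.549.

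**Figure D3:**
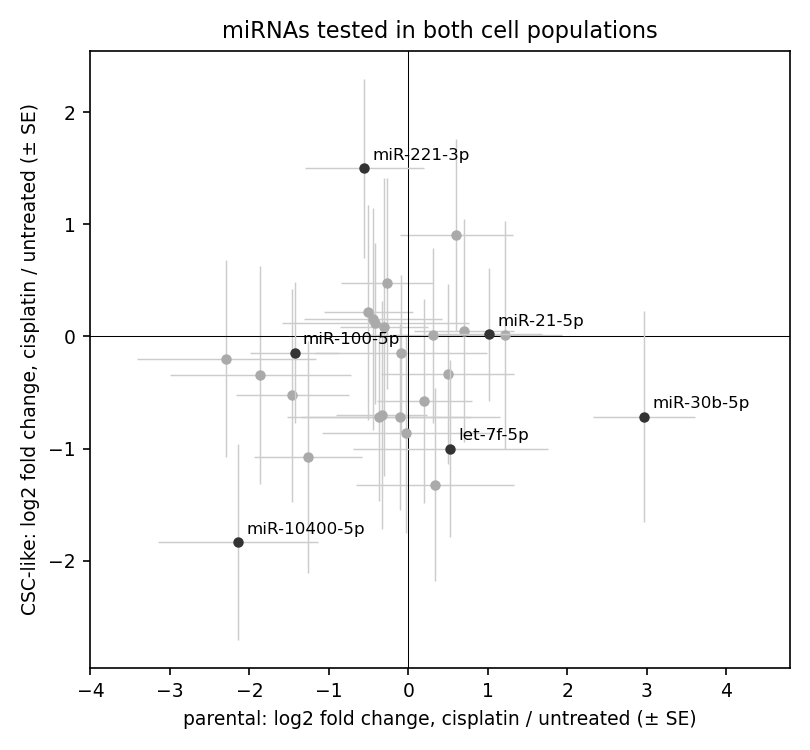
Log2 fold change with cisplatin in parental (horizontal axis) and CSC-like exosomes (vertical axis) of the 27 miRNAs tested in both tables, each with its SE as bars. miR-30b-5p lies apart at 2.97 and -0.72, and miR-3135b is not drawn because the count filter left it out of the parental test.

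The fourth comparison set untreated CSC-like against untreated parental exosomes, in a model of these 2 groups, on the miRNAs that both tables list. miR-30b-5p was higher in CSC-like exosomes, with 0.836% ± 0.451 against 0.0470% ± 0.0246 of counts (SD, n = 3 each) and a log2 fold change of 3.50 (SE 0.86, adjusted p = 0.00261, edgeR). It was higher in 3 of 3 CSC-like libraries than in any parental one. miR-100-5p (-1.81, SE 0.63, adjusted p = 0.0726), miR-25-3p (-2.34, SE 0.86, adjusted p = 0.0726), miR-7704 (-2.48, SE 1.05, adjusted p = 0.152) and miR-30c-5p (1.48, SE 0.67, adjusted p = 0.170) did not pass. Their values were named after they were seen. None of the tested let-7 members passed; let-7a-5p had a log2 fold change of -1.39 (SE 1.2), let-7b-5p of -0.33, let-7f-5p of 0.33, let-7g-5p of 0.07 and let-7i-5p of 0.06.

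Of the 30 miRNAs tested, 5 had an unadjusted p under 0.05, 2 higher and 3 lower in CSC-like exosomes. A contrast from the model over all 4 groups called 5, with miR-100-5p, miR-99b-5p, miR-25-3p and miR-7704 lower beside miR-30b-5p; leaving out untreated parental replicate 1 gave 0 calls (miR-30b-5p 3.41, adjusted p = 0.0801), untreated parental replicate 2 gave 4 and CSC-like replicate 1 gave 3. The populations are in separate tables, and whether they were sequenced together is not given in the sources used here, so population and batch cannot be told apart.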

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

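The tests of Y RNA matches, of counting error and of a general effect of cisplatin in this part were chosen after the result was seen, and the explanation by exact matches was narrowed to annotated transcripts after its test. The response of miR-3135b to cisplatin differed by 5.09 on the log2 scale between the 2 cell populations in a test of the difference itself, a call that was lost in 9 of 16 alternatives (3.13 to 5.88, adjusted p 0.0225 to 0.549) and at an adjusted p under 0.01. Its share was 4.21% to 6.29% of counts in cisplatin-treated CSC-like libraries and at most 0.378% elsewhere. The values argue against counting error, since the smallest exact lower bound with cisplatin lay 2.68 percentage points above the largest upper bound without it. In parental exosomes its mean share differed by -0.0147 percentage points with cisplatin, and the highest exact 95% upper bound of a treated library was 0.367%. These parental values argue against a rise of the size seen in CSC-like cells, but are part of the same difference and no separate test. A smaller rise in parental cells stays open. Its counts there were 1, 10 and 1 untreated and 6, 6 and 5 treated, so the untreated mean rests on replicate 2. No annotated transcript outside its own hairpin held the exact sequence (0 of 206694), but 10 Y RNA transcripts, RNY3 among them, held it at their 5' end with 2 mismatches, while 0 of the other 38 tested miRNAs had such a match to a transcript of that class. Reads from 5' fragments of Y3 RNA therefore stay open as a candidate source, since the mismatches that the authors' counting allowed are not given in the sources used here, and a rise of miR-3135b itself with cisplatin in CSC-like cells stays open as an untested biological hypothesis.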

How the results depend on the processing

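The alternatives that use separate or summed replicate pairs, library totals, a minimum of 15 counts, the 4-group contrast, the block on separate libraries, the block and leaving out libraries for the interaction, leaving out libraries for the lists, and all those for the untreated groups were chosen after seeing the data. Of 100 recomputed counts of calls, 72 stayed within 1.5 times the reported count, among them 2 stricter settings for camera that could not lower a count of 0, and 6 for fry without a CSC-like library, which could add a call but not end the 1 in parental cells. This compares the number of calls and not which miRNAs were called. Without untreated parental replicate 1, miR-30b-5p and miR-7-5p were not called in parental cells, but let-7a-5p and let-7b-5p were. For cisplatin in parental cells the 2 calls became 0 without the count filter and 0 to 8 on leaving out a library. For cisplatin in CSC-like cells the 1 call became 0 with a replicate block on the 3 separate libraries, and 0 to 1 on leaving out a library; without cisplatin-treated replicate 1 the lone remaining treated sample is assumed to vary like the other group. The interaction gave 0 calls at an adjusted p under 0.01, 0 with a replicate block on separate libraries, 2 with library totals and 0 to 1 on leaving out a library. Untreated CSC-like against parental gave 5 in the 4-group contrast and 0 to 4 on leaving out a library. Lists gave 0 calls by camera (0 at an unadjusted p under 0.05, and 1 call by fry), and 0 to 1 on leaving out a library, the 1 being a lower let-7 family without untreated parental replicate 1 (adjusted p = 0.0383). By fry the 1 call became 0 at an adjusted p under 0.01, 0 with a minimum log2 change of 1, 0 with every miRNA listed and 0 to 1 on leaving out a library. The cause of these changes was not tested. Leaving out a library also lowers the number of samples, and dropping the count filter also raises the number of miRNAs tested.

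Of 432 recomputed log2 fold changes of named miRNAs, 362 kept their direction and side of the threshold. Those that changed sign belong to miRNAs that were not called. In parental cells miR-4488 gave 0.29 with the replicate block, 0.13 with replicates 2 and 3 of the treated group as 1 sample and 0.0148 with library totals. let-7i-5p gave 0.17 without a filter, 1.07 with the block, 0.23 with library totals and 0.29 with at least 15 counts, and let-7g-5p 0.0562, 0.64, 0.18 and 0.18 under the same. On leaving out a library, miR-4488 ranged from -1.22 to 1.19, let-7i-5p from -0.65 to 1.81, let-7g-5p from -0.70 to 1.96, let-7f-5p from -0.0436 to 0.99 and miR-146a-5p from -0.76 to 1.02. In CSC-like cells DESeq2 gave 0.0772 for miR-100-5p, 0.0175 for let-7a-5p and 0.0498 for let-7i-5p. miR-4488 gave -0.20 without a filter, -0.33 with separate libraries, -0.51 with the block on them and -0.0713 with at least 15 counts, and miR-21-5p -0.00664 without a filter and -0.0593 with at least 15 counts. On leaving out a library, miR-100-5p ranged from -0.35 to 0.29, let-7a-5p from -0.36 to 0.19, let-7b-5p from -0.97 to 0.29, let-7i-5p from -0.33 to 0.23, miR-4488 from -1.96 to 1.30 and miR-21-5p from -0.0386 to 0.34.

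Whether equally numbered samples share a culture or batch is not given. Correlations of their deviations from group means do not settle it, since the deviations of 3 libraries from their mean are not independent. Deviations of equally numbered parental libraries correlated at 0.41, 0.44 and -0.01, and those of CSC-like libraries at -0.50, -0.52 and 0.20, and not every library correlated best with its own number. Across the populations, equally numbered untreated libraries correlated at -0.06, -0.45 and -0.23 and treated ones at 0.23, 0.12 and 0.02. Treated replicate 1 of either population correlated at between -0.22 and -0.16 with treated replicates 2 and 3 of the other. The block left the parental count at 2 and that of the untreated groups at 1. The pseudocount of 0.1 was not run, since no table holds normalized values. A depth of 429 to 6622 counts limits tests to about 27.0% of listed parental and 25.4% of listed CSC-like miRNAs.

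For the 2 calls in parental cells, 1 of 10 splits of the 6 libraries gave as many and the highest other split gave 0. For the 1 call between untreated groups, 2 of 10 splits gave as many and the highest other split gave 3. With 10 splits the share is never under 0.05.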

Other observations

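The tests of counting error, of swapped libraries and of the spread of the untreated parental libraries alone, with and without replicate 1, were chosen after the result was seen. Replicates 2 and 3 of both cisplatin-treated groups were close to each other and far from replicate 1. The chi-square per degree of freedom was 1.48 for that pair in parental and 1.18 in CSC-like exosomes, against 16.1 and 16.4, and 10.1 and 8.08, for the pairs with replicate 1. In both treated groups miR-4488 took more of replicate 1 (9.92% and 11.89%) than of replicates 2 and 3 (2.67% and 2.24%, 1.01% and 1.84%). miR-183-5p had 70 of 6622 counts in cisplatin-treated parental replicate 1, and 11 of 3552 and 17 of 3924 in replicates 2 and 3. miR-1246, whose sequence also occurs in 19 annotated snRNA transcripts, had 247 of 4005 counts in untreated parental replicate 3. The others of its group held 13 of 3527 and 29 of 2648.

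Untreated parental replicate 1 held little let-7, 0.851% of counts. Counting error is argued against, as the exact 95% upper bound was 1.21% and the lowest lower bound of replicates 2 and 3 was 13.6%. Loss of all miRNAs of similar GC content is argued against too, since 12 other tested miRNAs of 31.8% to 45.5% GC had a median log2 ratio to replicates 2 and 3 of -0.68 (range -3.27 to 0.29), against -4.59 for the 5 let-7 members. A swap with a cisplatin-treated parental library is argued against as the source of the low share, since the lowest lower bound among those libraries was 9.49%. A difference between cultures or preparations stays open, and no biological explanation was tested, since the design gives none within a group.

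Cisplatin-treated parental and untreated CSC-like exosomes differed from untreated parental exosomes in similar ways: across the 29 miRNAs tested in both comparisons the log2 fold changes correlated at 0.80, and 22 had the same sign (75.9%), with miR-30b-5p called in both (1 call, beside 0.034 from independent lists, which leaves out the shared libraries). The untreated parental libraries are in both comparisons, and the covariance of 1.16 lay above the highest of 100 simulations without effects (mean 0.37, highest 0.92), a bound set beforehand as the value against these libraries as the source. That bound was not kept, since it pooled dispersions (median 0.46) over both untreated groups, and those of the untreated parental libraries alone were larger (median 0.701). With the latter, 100 simulations had a mean covariance of 0.57 (95% range 0.17 to 1.05, highest 1.17), and 1 reached the observed value. In these simulations 2 gave a shared call, and the mean correlation was 0.57 with 67.5% of equal signs. Each miRNA was drawn independently, so this range does not cover miRNAs that vary together between libraries, as the let-7 family did. The spread of the 3 untreated parental libraries themselves gave a covariance of 0.67. The excess was 0.59 over the simulated mean and 0.49 over that spread. The 3 libraries cannot be split, so part of the excess may come from them and cannot be told apart from a shared effect. Without untreated parental replicate 1 the correlation was 0.81, above a bound of 0.5 set beforehand. That bound cannot decide on replicate 1. Simulations without effects, in which replicates 2 and 3 remained shared, had a mean correlation of 0.68 (95% range 0.43 to 0.87). The observed value was reached in 13 of these 100 simulations, so the shared libraries, replicate 1 among them, stay open. miR-30b-5p was called in neither comparison without replicate 1 (adjusted p = 0.139 and 0.0801, edgeR). Its log2 fold changes were then 2.73 and 3.41, against 2.97 and 3.50 with all libraries. A mix of miRNAs in CSC-like exosomes like that of parental cells after cisplatin stays open as a hypothesis.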
